A study of Homo sapiens with 24 samples.

How the data were processed

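Total RNA of dH1f cells was sequenced in 24 libraries, 3 for each of 8 groups: infected with the 4 factors or uninfected, each with VTP50469, DMSO, the guide MEN1 sg2 or the non-targeting guide NT1. The values used were the deposited expected counts per Ensembl gene, estimated counts that were already whole numbers. The submitters' processing notes name FastQC, MultiQC, STAR and Salmon without versions, and column names point to quantification with Salmon. The roles and order of these tools, the genome build and the annotation are not given in the sources used here, so no coordinates are printed. The table held 22777 genes, of which 22680 were matched to a symbol, and its lowest total over all libraries was 6 counts, so genes with fewer had been left out before. Library totals ran from 6562146 to 10642182 counts. A total count of 3 over a group was used as the floor for ratios against a group at 0, and such ratios cover counting error only.

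Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Counts would have been rounded first, which changed nothing here. Genes were kept by edgeR's filterByExpr by group, which left 15009, and libraries were scaled by TMM. A single model with 1 mean per group was fitted to all 24 libraries, with 16 residual degrees of freedom and a common biological coefficient of variation of 7.77%. Contrasts were tested with edgeR's robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all genes tested within each of 9 comparisons, and a gene was called at an adjusted p under 0.05. The comparisons were VTP50469 against DMSO and MEN1 sg2 against NT1, each in infected and in uninfected cells, infection within DMSO and within NT1 cells, the differences of the inhibitor and of the guide effect between infected and uninfected cells, and the difference between inhibitor and guide effects in infected cells. CPM values are means over a group with the SD, and fold changes in the text are ratios of mean CPM.

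For shared calls, the genes called in the same direction in a pair of comparisons were counted beside the number that independent lists of those sizes would share. Inhibitor and guide used separate control libraries, and each set of calls was compared with the infection effect of the other arm. The 30 gene lists, fixed with the comparisons, their alternatives and the rule for named genes before the data were examined, were tested with limma's camera at a preset correlation between genes of 0.01 and adjusted over the lists within a comparison. Each was tested again with the correlation estimated and with fry. Lists held 4 to 82 tested genes, and members were counted as called over all genes and as adjusted over the list alone.

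Named genes followed a fixed rule. In each comparison of 2 groups these were the 5 largest rises and 5 largest falls among called genes with a mean of at least 2 CPM and no overlap between the groups, which chance gives for 10% of genes with 3 libraries against 3. To these were added a fixed set (MEN1, KMT2A, POU5F1, SOX2, KLF4, MYC, NANOG, LIN28A, CDH1, EPCAM, COL1A1, TWIST1, CDKN1A, MKI67, HOXA9 and MEIS1) and the 2 called members with the smallest p of each list called by camera. For interactions the 3 largest changes each way were taken, where the criterion of groups without overlap was not applied, and for shared calls the 5 highest and 5 lowest genes. Pseudogenes, genes without a symbol, and several classes of noncoding and mitochondrial names were skipped. HOXB2, which lies outside that rule, was chosen after its values were seen. For the inhibitor in infected cells HOXD11 lies outside it too, and is given there as the upper end of the range of HOX genes. Some genes that the rule picked are not reported here and were not replaced.

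Alternatives were DESeq2 size factors and upper quartile factors in place of TMM, no filter on low counts, DESeq2's Wald test, a fit of the compared groups only, the replicate number as a block, and each library left out in turn. A fit without the library uninfected MEN1 sg2 replicate 2 was added after the data were examined, because that library stood apart from its group. Transcript lengths and gene names came from GENCODE v29, used only for names, gene classes and lengths.

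The fit was tested on simulated data with 200 of 15009 genes changed. Of changes of 0.5, 1 and 2 on the log2 scale, 56.7%, 74.6% and 90.9% were called for the inhibitor in infected cells and 26.9%, 56.7% and 81.8% in its interaction with infection, and 8.07% and 4.35% of those calls were false. None of 50 unchanged lists was called by camera. In these simulations genes varied independently, so they do not measure the effect of correlation between genes. Other splits of the same libraries, which mixed the compared groups wholly or in part, were used to count how often they gave as many calls.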

Results

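RNA was sequenced from dH1f cells, human fibroblasts obtained by differentiating the H1 embryonic stem cell line, in 24 libraries that made up 8 groups of 3. The study asked how inhibition or loss of menin changes gene expression in fibroblasts, with and without the factors that reprogram them towards pluripotency. Menin, encoded by MEN1, is a cofactor of the histone methyltransferase MLL1 (KMT2A). In the drug arm, cells received 1 µM VTP50469, an inhibitor of the MLL1-menin interaction, or DMSO. In the guide arm, cells that expressed Cas9 carried a guide RNA against MEN1 (MEN1 sg2) or a non-targeting guide (NT1). Each arm held cells infected with lentiviruses that carried OCT4 (POU5F1), SOX2, KLF4 and c-MYC (OSKM) and cells left uninfected. The drug was added 1 day after infection, and RNA was collected at the end of 6 days.

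The estimated counts summed to between 6562146 and 10642182 per library over 22777 genes, of which 15009 had enough counts to be tested. Infection was the main axis of the data: the first principal component held 66.8% of the variance and placed all infected libraries on one side and all uninfected libraries on the other. The second component held 6.96% and ordered the treatments alike in infected and uninfected cells. Its group means in infected cells were -26.0 with NT1, -14.5 with DMSO, 4.86 with VTP50469 and 32.2 with MEN1 sg2. In uninfected cells they were -23.3, -12.5, 5.84 and 33.4 in the same order, with SDs of 1.02 to 2.92 over the 8 groups. The 15 genes with the most counts, led by the matrix genes FN1 and COL1A1, took 18.8% to 20.6% of the counts in uninfected groups and 11.5% to 13.4% in infected ones.

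Replicates of every group differed by more than counting noise. The chi-square per degree of freedom between replicates lay between 2.21 and 4.4, except in the pairs that held the library uninfected MEN1 sg2 replicate 2, where it was 13.6 and 15.2. That library held fewer counts of genes with long transcripts, with a correlation of -0.25 across genes between its deviation from the mean of the other two of its group and transcript length. The counts of genes called in the drug arm rose by more than 1.5-fold in a fit without it, so these are given beside the main ones. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

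MEN1 (ENSG00000133895), the target of the guide, was lower in every library with MEN1 sg2 than in every library with NT1. In infected cells it stood at 12.8 ± 0.34 CPM (counts scaled to library size; SD, n = 3) with MEN1 sg2 and 36.7 ± 1.3 with NT1, a 2.86-fold fall. In uninfected cells it stood at 15.9 ± 1.1 against 38.2 ± 1.9, a 2.41-fold fall. The adjusted p of edgeR's quasi-likelihood test was 3.8e-15 in infected and 5e-13 in uninfected cells. VTP50469 acts on the protein, and MEN1 transcript was not called different with it: 40.7 ± 3.3 against 37.1 ± 0.44 CPM in infected cells (adjusted p = 0.46) and 44.5 ± 3.2 against 39 ± 0.99 CPM in uninfected cells (adjusted p = 0.28). KMT2A was not called in any of these 4 comparisons and ran at 101 ± 7.5 CPM with MEN1 sg2 and 95.3 ± 15 CPM with NT1 in infected cells.

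**Figure D1:**
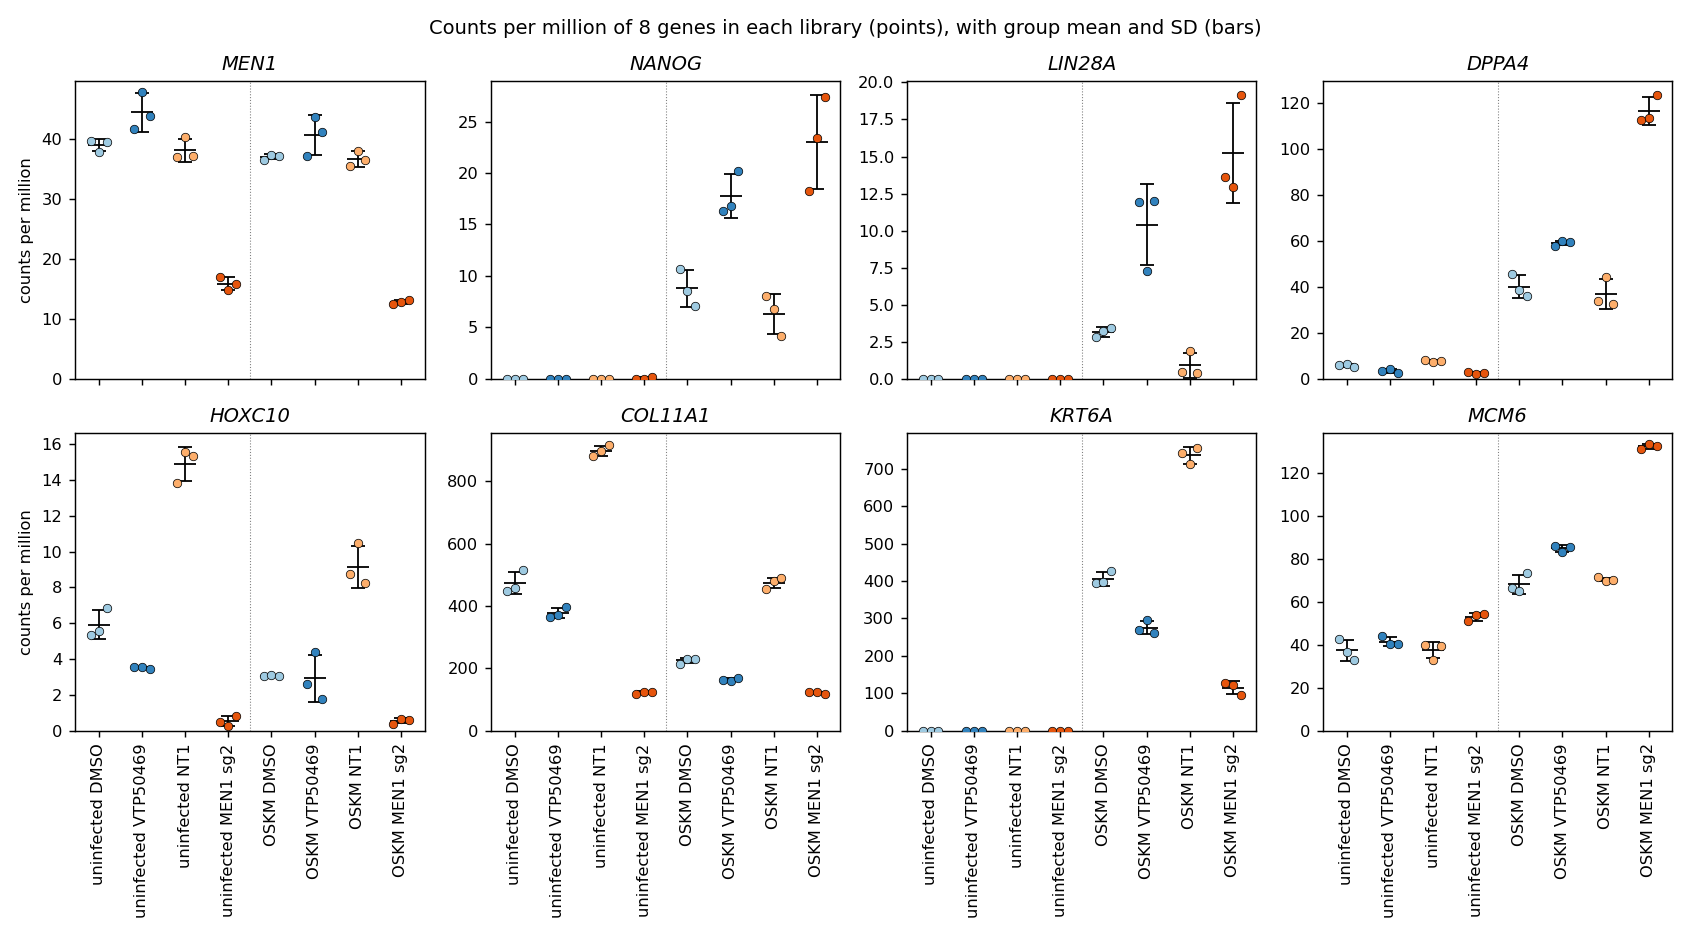
CPM, counts scaled to library size, of MEN1, NANOG, LIN28A, DPPA4, HOXC10, COL11A1, KRT6A and MCM6 in each of the 24 libraries (points), with the mean and SD of each group of 3 (bars); the dotted line parts uninfected from infected groups. MEN1 fell to 12.8 and 15.9 CPM with its guide, and NANOG in infected cells rose from 8.77 to 17.8 CPM with VTP50469 and from 6.31 to 23 CPM with MEN1 sg2.

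The effect of infection with the reprogramming factors was read from the control cells of each arm. No group received a virus without the factors, so effects of the factors cannot be told apart from those of infection itself. After 6 days infected cells had higher levels of pluripotency, keratin and neural transcripts, several of them at 0 counts in uninfected cells, and lower levels of contractile, matrix and mesenchymal surface transcripts. NANOG, a transcription factor of pluripotent cells, was at 0 counts in uninfected DMSO and NT1 cells and at 8.77 ± 1.8 CPM with DMSO and 6.31 ± 2 CPM with NT1 after infection, at least 68.1-fold and 46.6-fold higher. The keratin KRT14 went from 0 counts to 888 ± 2.3 and 998 ± 66 CPM, at least 6940-fold and 7340-fold higher. COL1A1, the main chain of type I collagen, fell 1.86-fold and 1.69-fold, to 21800 ± 330 and 22200 ± 180 CPM.

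With DMSO 4385 genes rose and 3833 fell on infection, and with NT1 4318 rose and 3788 fell. Of these, 3537 rose and 3097 fell in both arms, where independent lists would share 1262 and 967, and 16 went opposite ways. The log2 fold changes of the 2 arms correlated across genes, which are not independent replicates, with a Pearson coefficient of 0.899. The 4 factor genes rose in both arms. KLF4 rose 18.5-fold to 358 ± 8.4 CPM with DMSO and 22.7-fold to 421 ± 6.7 CPM with NT1, and MYC rose 4.84-fold and 7.52-fold. POU5F1 was at 124 ± 11 CPM and SOX2 at 111 ± 4 CPM in infected DMSO cells, against 0 counts in uninfected ones. These counts cannot separate vector from endogenous transcript.

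Of the 22 pluripotency genes tested, 18 rose and none fell in each arm, with 19 and 18 risen when adjusted over the list alone. L1TD1, an RNA-binding protein of embryonic stem cells, rose 85.3-fold and 45-fold, and PODXL, a sialomucin, rose 9.07-fold and 7.17-fold. Squamous keratinocyte genes rose in 13 of 15 in each arm. The leading keratins KRT14, KRT16, KRT17 and KRT6A belong to a family of close paralogs whose reads may be shared. Epithelial genes rose in 18 of 26 with DMSO and 20 of 26 with NT1: JUP, a junction protein, rose 13-fold and 13.4-fold, and CDH1, E-cadherin, 24.6-fold and 6.88-fold. Neural genes rose in 8 of 10 in each arm, STMN2 to 94.9 ± 4.2 and 81.6 ± 8 CPM. Of 10 endothelial genes 6 and 8 rose, among them the angiopoietin receptor TEK, to 173 ± 6.3 and 171 ± 11 CPM. All of these lists were called by limma's camera, also with an estimated correlation between genes. Of the 8 skeletal muscle genes 5 rose with DMSO and 4 with NT1, where the call was lost with an estimated correlation (adjusted p = 0.055). Members silent in uninfected cells could pass the filter on low counts only through infected libraries, and could then hardly fall. The shares that rose and the list calls of this paragraph are thus partly set by the filter. Of 30 pluripotency genes listed 22 were tested, and of 21 neural genes 10.

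Contractile and TGF-beta response genes fell in 22 of 25 with DMSO and 20 of 25 with NT1, among them the tropomyosin TPM1, 3.18-fold and 3.02-fold lower. Collagen and matrix genes fell in 27 of 36 and rose in 9 of 36 in each arm; LOXL2, which cross-links collagen, fell 4.44-fold and 3.87-fold. Mesenchymal surface genes fell in 13 of 18, with the collagen receptor ITGA11 4.33-fold and 4.6-fold lower. These 3 lists were called in both arms with an estimated correlation as well. Glycolysis and hypoxia genes fell in 25 of 28 with DMSO (adjusted p = 0.062 with an estimated correlation) and 19 of 28 with NT1 (adjusted p = 0.22 with an estimated correlation), and BNIP3, a mitophagy receptor induced by hypoxia, fell 5.46-fold and 5.1-fold. S phase genes rose in 24 of 34 and 28 of 34, with MCM3, a subunit of the replicative helicase, 1.9-fold and 1.99-fold higher. Their camera calls were lost with an estimated correlation (adjusted p = 0.23 with DMSO and 0.17 with NT1). Mitosis genes rose in 20 of 34 with NT1 (adjusted p = 0.53 with an estimated correlation) and went both ways with DMSO, 10 up and 6 down. Inflammatory and secretory genes split, 8 up and 10 down with DMSO and 6 up and 9 down with NT1. With DMSO camera placed that list lower while its median and mean log2 fold changes were 0.138 and 0.151, and the estimated correlation gave an adjusted p of 0.058 there and 0.048 with NT1. HOX genes were not called as a list, although 8 of 18 fell with DMSO and 6 of 18 with NT1.

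The inhibitor was first read in infected cells, to ask how blocking menin alters the early response to infection with the factors. Pluripotency and S phase transcripts rose with VTP50469, and squamous and inflammatory transcripts fell, with those of KLF4 and MYC among the 4 factors. NANOG was 2.03-fold higher with the drug, at 17.8 ± 2.1 against 8.77 ± 1.8 CPM (n = 3), and LIN28A, which blocks let-7 maturation, was 3.32-fold higher, at 10.4 ± 2.7 against 3.14 ± 0.33 CPM. In all, 346 genes rose and 392 fell by edgeR's quasi-likelihood test, 55 and 23 of them by at least 2-fold.

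Of the 22 pluripotency genes, 11 rose and none fell (13 up and 1 down adjusted over the list alone), with an adjusted p of 0.0037 with an estimated correlation. LEFTY2, a Nodal antagonist, rose 2.05-fold (adjusted p = 9.2e-05) and the noncoding RNA ESRG 1.72-fold (adjusted p = 1.1e-05). S phase genes rose in 13 of 34 (22 adjusted over the list alone; adjusted p = 0.0037 with an estimated correlation), with POLE, a DNA polymerase subunit, 1.34-fold higher. No mitosis gene of 34 was called, and the camera call of that list was lost with an estimated correlation (adjusted p = 0.32). Transcripts of 2 of the 4 factors fell (2 adjusted over the list alone; adjusted p = 0.0037 with an estimated correlation): KLF4 from 358 ± 8.4 to 271 ± 7.2 CPM and MYC from 477 ± 18 to 361 ± 9 CPM, each 1.32-fold. POU5F1 (115 ± 4.3 against 124 ± 11 CPM) and SOX2 (105 ± 6.4 against 111 ± 4 CPM) were not called.

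Squamous keratinocyte genes fell in 5 of 15 (5 adjusted over the list alone; adjusted p = 0.029 with an estimated correlation), KRT14 by 1.35-fold. Inflammatory and secretory genes fell in 5 of 22 (6 adjusted over the list alone; adjusted p = 0.0085 with an estimated correlation), with the adhesion molecule ICAM1 1.6-fold and the cytokine LIF 1.4-fold lower. Interferon response genes had a median log2 fold change of -0.70, but 1 of 36 was called (15 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). The camera calls of 5 further lists were lost with an estimated correlation. Mesenchymal transcription factors rose in 2 and fell in 4 of 33 (adjusted p = 0.13), with RUNX2, a regulator of bone formation, 1.46-fold lower. Mesenchymal surface genes rose in 1 and fell in 4 of 18 (adjusted p = 0.19), with the TGF-beta coreceptor ENG 1.35-fold lower. Antigen presentation genes fell in 3 of 19 (adjusted p = 0.19), ATF4 and unfolded protein response genes in 4 of 27 (adjusted p = 0.26), and cholesterol synthesis genes rose in 2 of 25 (adjusted p = 0.21). Collagen and matrix genes moved both ways, 6 up and 7 down of 36, and 1 of 18 HOX genes fell. Camera called neither list in the main fit. HOX genes had log2 fold changes from -2.91 (HOXA13) to 0.62 (HOXD11), and fry called that list (adjusted p = 0.00966).

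Besides LIN28A, the largest rises were those of MCHR1, the melanin-concentrating hormone receptor (6 ± 0.64 against 1.26 ± 0.38 CPM, 4.77-fold), NTS, neurotensin (3.39 ± 0.72 against 0.805 ± 0.65 CPM), PTPRZ1, a receptor phosphatase (3.43-fold), and SLC17A8, a vesicular glutamate transporter (12.8 ± 0.49 against 3.83 ± 0.27 CPM, 3.35-fold). NTS was no longer called without OSKM VTP50469 replicate 3 (adjusted p = 0.069) or OSKM DMSO replicate 2 (adjusted p = 0.078) or 3 (adjusted p = 0.094), and DESeq2 gave it no adjusted p. Neural genes, 2 up and 1 down of 10, were not called as a list. The largest falls included BCHE, butyrylcholinesterase (4.89-fold), MAB21L2 (6.65 ± 0.33 against 23.2 ± 1.2 CPM, 3.49-fold) and LGR5, an R-spondin receptor (2.63-fold). Without the library uninfected MEN1 sg2 replicate 2 in the shared fit, 521 genes rose and 637 fell, and with only the compared groups fitted 660 and 861. With any 1 of the 6 compared libraries left out, 157 to 222 rose and 222 to 286 fell.

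In uninfected fibroblasts, which showed the action of the inhibitor without the factors, VTP50469 raised cholesterol synthesis and S phase transcripts and lowered mesenchymal regulators. HMGCS1, an early enzyme of cholesterol synthesis, rose 1.39-fold to 136 ± 5 CPM. TWIST1, a mesenchymal transcription factor, fell 1.53-fold, from 27.5 ± 2.3 to 18 ± 1.9 CPM (adjusted p = 0.00012). NANOG, LIN28A, POU5F1 and SOX2 had 0 counts in all 6 libraries. Altogether 172 genes rose and 307 fell, 21 and 50 by at least 2-fold.

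Cholesterol synthesis genes rose in 8 of 25 (14 adjusted over the list alone; adjusted p = 0.0044 with an estimated correlation), and S phase genes in 9 of 34 (15 adjusted over the list alone; adjusted p = 0.014). Mitosis genes rose in 5 of 34 (13 adjusted over the list alone), a list call lost with an estimated correlation (adjusted p = 0.056). Mesenchymal transcription factors fell in 5 of 33 (6 adjusted over the list alone; adjusted p = 0.021 with an estimated correlation), led by MKX, a tendon regulator (5.71 ± 1.2 against 17.6 ± 4.3 CPM, 3.08-fold), and PRRX1 (1.33-fold). The homeobox gene MEOX2 fell 3.42-fold. Inflammatory and secretory genes fell in 5 of 22 (7 adjusted over the list alone; adjusted p = 0.014 with an estimated correlation), VCAM1 by 2.63-fold and IGFBP3, which binds insulin-like growth factors, by 1.38-fold. No HOX gene was called over all genes and 3 of 18 fell when adjusted over the list alone; the list as a whole stood lower, with a median log2 fold change of -0.68 and an adjusted p of 0.0059 with an estimated correlation. Interferon response genes had 0 of 36 called and 10 lower when adjusted over the list alone, with a median of -0.71 and an adjusted p of 0.31 with an estimated correlation. Ribosomal protein genes (1 of 82 up; adjusted p = 0.44), immediate early genes (0 of 18; adjusted p = 0.31) and antigen presentation genes (0 of 19; adjusted p = 0.44) also lost their camera calls with an estimated correlation.

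The largest falls included FRRS1L, an AMPA receptor component (1.55 ± 0.34 against 7.54 ± 1.9 CPM, 4.87-fold), and MAB21L2 (12.4 ± 0.46 against 41 ± 7.6 CPM, 3.31-fold), and the largest rises included the growth factor IGF2 (5.09 ± 0.14 against 1.46 ± 0.49 CPM, 3.5-fold) and MGAM, maltase-glucoamylase (3.02-fold). Without the library uninfected MEN1 sg2 replicate 2 in the fit, 349 genes rose and 529 fell. Leaving out any 1 of the 6 compared libraries gave 97 to 119 risen and 180 to 249 fallen genes.

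The MEN1 guide was compared with NT1 in infected cells, the genetic counterpart of the drug comparison. Loss of MEN1 transcript came with higher pluripotency, S phase and mitosis transcripts and lower HOX, squamous, inflammatory, contractile and matrix transcripts. LIN28A rose 16.9-fold (15.2 ± 3.4 against 0.902 ± 0.83 CPM, n = 3), NANOG 3.64-fold (23 ± 4.6 against 6.31 ± 2 CPM) and DPPA4, a chromatin-associated protein of pluripotent cells, 3.16-fold (116 ± 6 against 36.9 ± 6.4 CPM). HOXC10 fell 16.8-fold, from 9.14 ± 1.2 to 0.545 ± 0.14 CPM, and KRT6A 6.39-fold, from 736 ± 22 to 115 ± 16 CPM. By the same test 2305 genes rose and 2435 fell, 451 and 584 of them by at least 2-fold.

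All 34 S phase genes and all 34 mitosis genes rose, the same numbers as adjusted over the list alone (adjusted p = 0.00014 and 0.0025 with an estimated correlation). TYMS, thymidylate synthase, rose 2.23-fold, MCM6 1.88-fold, the cyclin CCNA2 1.95-fold and the kinesin KIF2C 2-fold. Of the pluripotency genes 16 rose and 2 fell of 22 (17 and 2 adjusted over the list alone; adjusted p = 0.0025 with an estimated correlation). POU5F1 rose 1.23-fold to 184 ± 5.6 CPM and SOX2 1.18-fold to 163 ± 8.4 CPM, while KLF4 fell 1.51-fold and MYC 1.58-fold; SOX2 was no longer called without OSKM NT1 replicate 2 (adjusted p = 0.061) or 3 (adjusted p = 0.13) or OSKM MEN1 sg2 replicate 1 (adjusted p = 0.087). Cholesterol synthesis genes rose in 15 of 25 (15 adjusted over the list alone; adjusted p = 0.016). Neural genes rose in 5 and fell in 4 of 10 (adjusted p = 0.058 with an estimated correlation); the intermediate filament NES rose 3.06-fold to 222 ± 8.5 CPM.

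HOX genes fell in 17 of 18 (17 adjusted over the list alone), with a median log2 fold change of -2.92 and an adjusted p of 1e-04 with an estimated correlation. HOXA9 fell 6.07-fold (1.09 ± 0.57 against 6.6 ± 1.8 CPM) and HOXA10 5.58-fold. Squamous keratinocyte genes fell in 11 of 15 (11 adjusted over the list alone; adjusted p = 1e-04). Inflammatory and secretory genes fell in 13 of 22 (14 adjusted over the list alone; adjusted p = 0.00014), LIF by 4.2-fold. Contractile and TGF-beta response genes fell in 14 and rose in 3 of 25 (16 and 3 adjusted over the list alone; adjusted p = 0.0025), with CCN2, a matricellular growth factor, 1.97-fold lower. Collagen and matrix genes fell in 26 and rose in 6 of 36 (adjusted p = 0.011), COL11A1 by 3.88-fold (122 ± 3.3 against 474 ± 17 CPM) and COL1A1 by 1.36-fold. Mesenchymal surface genes fell in 11 and rose in 3 of 18 (adjusted p = 0.016), with the fibroblast protease FAP at 33.3 ± 1.3 against 66.8 ± 5.9 CPM. The list p-values of this paragraph were taken with an estimated correlation.

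Interferon response genes fell in 30 of 36 (32 adjusted over the list alone), but their camera call was lost with an estimated correlation (adjusted p = 0.26). Their mean log2 CPM was 4.11, 4.27 and 3.86 in the MEN1 sg2 libraries and 4.95, 5.06 and 5.77 in the NT1 libraries. The same held for mesenchymal transcription factors (15 down and 3 up of 33; adjusted p = 0.058), led by TBX15 (8.13-fold lower), for antigen presentation genes (12 of 19 down; adjusted p = 0.09), for ATF4 and unfolded protein response genes (13 down and 1 up of 27; adjusted p = 0.11), led by the amino acid transporter SLC7A5 (2.03-fold lower), and for mitochondrially encoded genes (7 of 13 down; adjusted p = 0.49). Other lists were not called: epithelial genes (4 up and 10 down of 26), p53 target genes (6 and 11 of 27), glycolysis and hypoxia genes (6 and 9 of 28), immediate early genes (2 and 5 of 18), subunits of MLL and related complexes (6 and 1 of 20), other reported targets of menin and MLL1 (6 and 2 of 16), ribosomal protein genes (9 and 1 of 82), replication-dependent histone genes (0 and 5 of 21), endothelial genes (1 and 3 of 10), skeletal muscle genes (1 and 1 of 8) and trophoblast genes (3 and 2 of 6). None of the 4 blood cell or 4 endoderm genes was called. Genes with the largest changes included CKM, the muscle creatine kinase (31.8-fold lower), the transcription factor PAX8 (14.6-fold lower) and IL18R1, an interleukin receptor (25.3-fold higher). Counts fell by less than 1.5-fold whichever of the 6 libraries was left out.

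**Figure D2:**
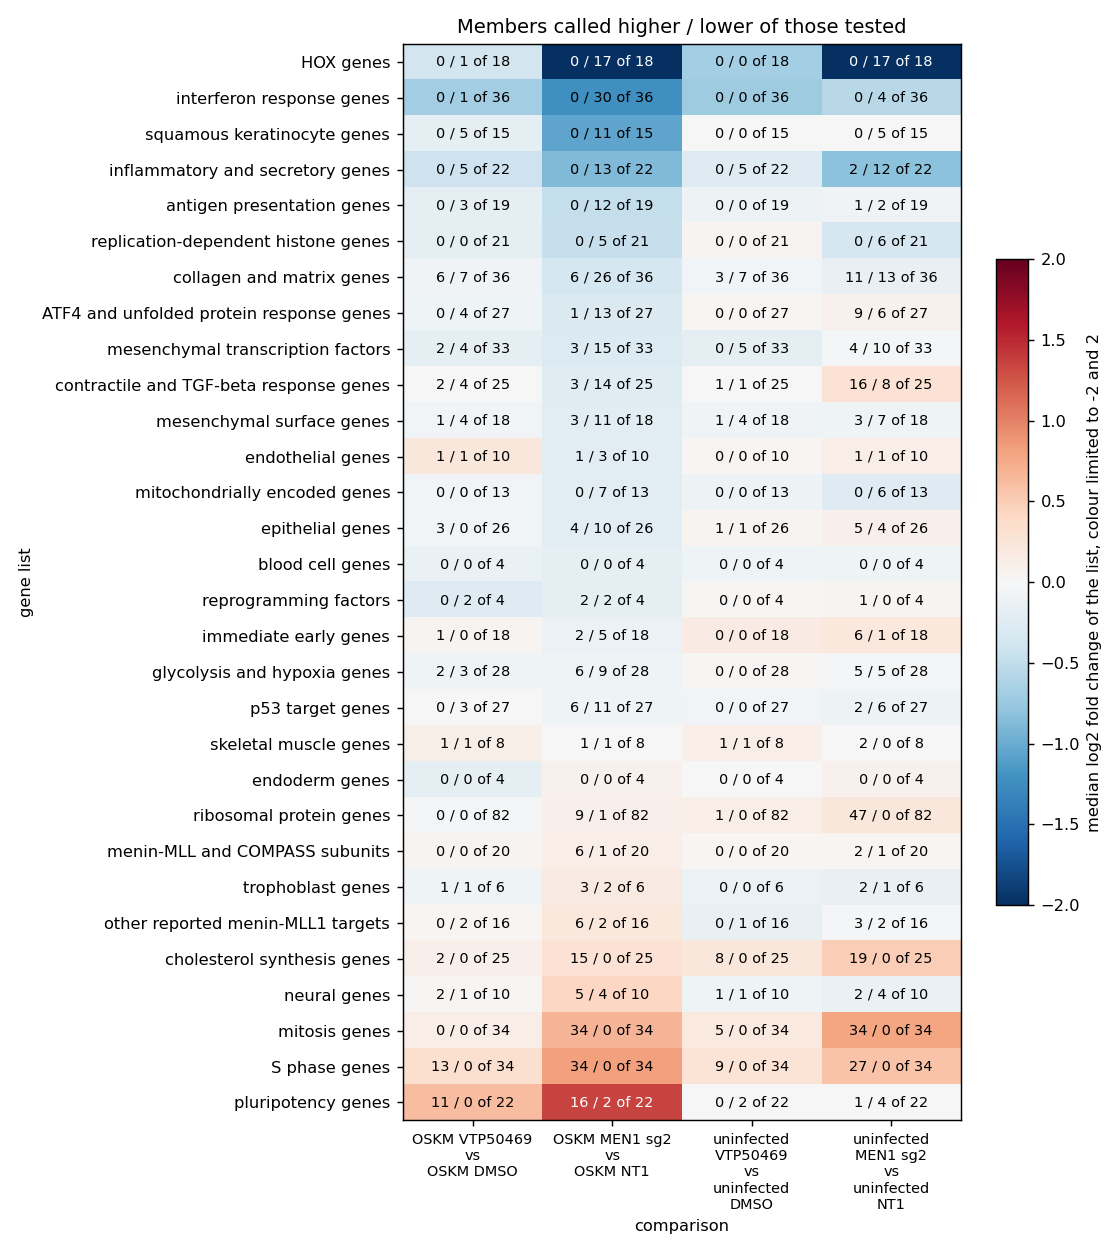
Median log2 fold change (colour, limited to -2 and 2) of 30 gene lists in the 4 treatment comparisons, with the number of members called higher and lower of those tested written in each cell; genes with 0 counts in a group were set at their bound. HOX genes had 17 of 18 members lower with MEN1 sg2 in infected and in uninfected cells, and pluripotency genes had 11 and 16 of 22 higher with VTP50469 and MEN1 sg2 in infected cells.

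The same guide was compared with NT1 in uninfected fibroblasts. Mitosis, S phase and cholesterol synthesis transcripts rose and HOX and inflammatory transcripts fell. HOXC10 fell 28.8-fold (0.518 ± 0.28 against 14.9 ± 0.94 CPM, n = 3), and HOXA13, with 3 counts over the group, was at 0.0139 times its NT1 level (95% exact interval 0.00284 to 0.0411, counting error only). COL11A1 fell 7.34-fold, from 897 ± 18 to 122 ± 3.6 CPM. ACTA2, smooth muscle actin, rose 2.09-fold to 1390 ± 130 CPM and CNN1, calponin, 2.42-fold to 332 ± 34 CPM. In total 1856 genes rose and 1760 fell, 295 and 505 by at least 2-fold. With only the compared groups fitted, 936 rose and 1116 fell.

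HOX genes fell in 17 of 18 (17 adjusted over the list alone), with a median log2 fold change of -3.59 as fitted and -3.50 with the gene at 0 counts set at its bound, and an adjusted p of 2.8e-06 with an estimated correlation. All 34 mitosis genes rose (34 adjusted over the list alone, list adjusted p = 0.00098), with the kinesin KIF20A 2.02-fold and the spindle factor TPX2 1.59-fold higher. Among them MKI67 lost its call without uninfected NT1 replicate 1 (adjusted p = 0.06) or uninfected MEN1 sg2 replicate 1 (0.068) or 3 (0.1). It also lost it with the replicate block (0.07) and with only the compared groups fitted (0.28). S phase genes rose in 27 of 34 (29 adjusted over the list alone; adjusted p = 0.012) and cholesterol synthesis genes in 19 of 25 (20 adjusted over the list alone; adjusted p = 0.00098), with HMGCS1 1.93-fold higher. Inflammatory and secretory genes fell in 12 and rose in 2 of 22 (adjusted p = 0.00098), LIF by 3.56-fold. Neural genes fell in 4 and rose in 2 of 10 (adjusted p = 0.039), and the adhesion molecule L1CAM fell 6.45-fold to 36.2 ± 5.3 CPM. The list p-values of this paragraph too were taken with an estimated correlation.

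Contractile and TGF-beta response genes rose in 16 and fell in 8 of 25 (adjusted p = 0.16 with an estimated correlation), collagen and matrix genes rose in 11 and fell in 13 of 36 (adjusted p = 0.27) and mesenchymal transcription factors rose in 4 and fell in 10 of 33 (adjusted p = 0.27), with TBX15 12.7-fold and MKX 10.3-fold lower. Mesenchymal surface genes rose in 3 and fell in 7 of 18 (adjusted p = 0.27). Ribosomal protein genes rose in 47 of 82 (60 adjusted over the list alone; adjusted p = 0.56), RPL5 by 1.23-fold. They took 4.39% of the counts in uninfected MEN1 sg2 replicate 2, 3.28% and 3.34% in the other two of that group and at most 3.16% with NT1. Mitochondrially encoded genes fell in 6 of 13 (adjusted p = 0.56). Interferon response genes fell in 4 of 36 (1 adjusted over the list alone; adjusted p = 0.87), and their mean log2 CPM ran from 3.74 to 5.30 in the NT1 libraries and from 3.92 to 4.53 in the MEN1 sg2 libraries. In a fit without the library that held fewer counts of long transcripts, uninfected MEN1 sg2 replicate 2, camera no longer called mesenchymal transcription factors (adjusted p = 0.149), mesenchymal surface genes (adjusted p = 0.124) or mitochondrially encoded genes (adjusted p = 0.0507).

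Of the factor genes KLF4 was called 1.24-fold higher (23.1 ± 1.9 against 18.6 ± 3.1 CPM), a call lost without uninfected NT1 replicate 1 (adjusted p = 0.24) or uninfected MEN1 sg2 replicate 3 (adjusted p = 0.12) or with only the compared groups fitted (adjusted p = 0.23), and NANOG, LIN28A, POU5F1 and SOX2 had at most 1 count over each group of 3. CDKN1A, a cell cycle inhibitor, fell 1.31-fold to 47.5 ± 1.7 CPM. The largest changes included falls of PAX8 (40-fold, to 0.739 ± 0.46 CPM) and MEOX2 (30.4-fold, to 0.436 ± 0.2 CPM) and rises of the netrin receptor UNC5C (14.2-fold, to 6.41 ± 1.1 CPM) and the adhesion receptor ADGRB1 (11.7-fold, to 7.4 ± 1.1 CPM). IGF2 rose 7.83-fold, to 16.7 ± 2.5 CPM.

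Whether each treatment acted differently in infected and uninfected cells was tested with an interaction term. For the guide, 871 genes had a higher log2 fold change in infected than in uninfected cells and 1020 a lower one. Most genes called in infected and in uninfected cells still moved alike, 817 up and 929 down, where independent lists would share 285 and 286, and 271 went opposite ways. The list with the smallest p was that of contractile and TGF-beta response genes: 18 of 25 had a lower effect in infected than in uninfected cells and 1 a higher one (20 and 1 adjusted over the list alone; adjusted p = 8.8e-05 with an estimated correlation). Neural genes had a higher effect in 3 of 10 (6 adjusted over the list alone; adjusted p = 0.00022). PTPRZ1 rose from 1.47 ± 0.3 to 13.8 ± 2.4 CPM with the guide in infected cells and had 7 counts with NT1 and 0 with MEN1 sg2 in uninfected cells (interaction 7.67 on the log2 scale, adjusted p = 0.00027). The camera calls of 11 further lists on this interaction were lost with an estimated correlation, among them pluripotency genes (7 of 22 higher; adjusted p = 0.17), collagen and matrix genes (17 lower and 6 higher of 36; adjusted p = 0.17) and ATF4 and unfolded protein response genes (14 lower and 1 higher of 27; adjusted p = 0.17).

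For the inhibitor, 66 genes had a higher and 73 a lower effect in infected than in uninfected cells. Of the genes called in each, 30 rose and 89 fell in both (expected 3.97 and 8.02), and 10 went opposite ways. The growth factor gene IGF2 had a lower effect in infected cells: with the drug it went from 1.46 ± 0.49 to 5.09 ± 0.14 CPM in uninfected cells and from 2410 ± 59 to 2220 ± 170 CPM in infected cells (interaction -1.92, adjusted p = 8.1e-06). The zinc finger gene ZNF483 went the other way, with 7.14 ± 0.97 and 13.2 ± 1 CPM in infected DMSO and VTP50469 cells and 1.37 ± 0.12 and 0.456 ± 0.34 CPM in uninfected ones (interaction 2.46, adjusted p = 0.0094); its call was lost without uninfected VTP50469 replicate 1 (adjusted p = 0.059). None of the 7 lists called by camera held with an estimated correlation, where the smallest adjusted p was 0.13. Without the library uninfected MEN1 sg2 replicate 2 in the fit, 159 genes were called upward and 218 downward, with only the compared groups fitted 150 and 210, and leaving out any 1 of the 12 compared libraries gave 32 to 58 and 30 to 60.

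Drug and guide were compared in 2 ways, by the genes called with both and by a test of the difference between their effects in infected cells. In infected cells 276 genes rose and 340 fell with both, where independent lists of these sizes would share 53.1 and 63.6, and 6 went opposite ways. The arms have separate control libraries. LIN28A, MCHR1, SLC17A8, PTPRZ1 and the adaptor gene SHC2 led the shared rises, and MAB21L2, BCHE and LGR5 were among the 5 leading shared falls. MAB21L2 fell 3.49-fold with the drug and 4.09-fold with the guide. The log2 fold changes of drug and guide correlated across genes with a Pearson coefficient of 0.298 and a Spearman coefficient of 0.459. In uninfected cells 132 genes rose and 236 fell with both (expected 21.3 and 36), and 7 went opposite ways; MEOX2, MAB21L2, FRRS1L, MKX and the laminin chain LAMA2 led the falls and IGF2 was among the leading rises. In a fit without uninfected MEN1 sg2 replicate 2, infected cells shared 400 rises and 525 falls with 22 opposite, and uninfected cells 204 rises and 316 falls with 23 opposite. With any 1 of the 12 compared libraries left out, infected cells shared 139 to 263 rises and 207 to 339 falls. In uninfected cells the fewest shared rises were 75, without uninfected VTP50469 replicate 2, and the fewest shared falls 136, without uninfected VTP50469 replicate 3.

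**Figure D3:**
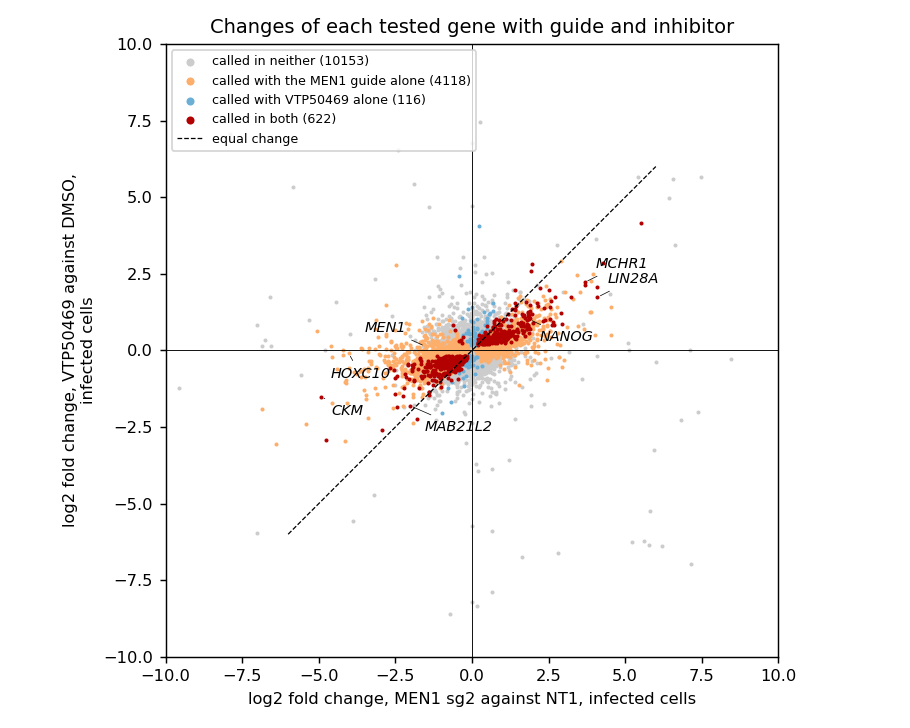
Log2 fold change of each of 15009 tested genes in infected cells with MEN1 sg2 against NT1 (horizontal) and with VTP50469 against DMSO (vertical), coloured by the comparisons in which the gene was called; the dashed line marks equal changes. Of 622 genes called with both, 616 went the same way, and 4118 were called with the guide alone and 116 with the inhibitor alone.

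The difference between the effects of drug and guide in infected cells was called in 776 genes where the drug effect was the higher and 582 where it was the lower (1057 lower with only the compared groups fitted). HOX genes stood out: 11 of 18 had a higher effect with the drug and none a lower one (14 adjusted over the list alone; adjusted p = 8.1e-05 with an estimated correlation). HOXC10 was at 2.93 ± 1.3 with VTP50469 and 3.07 ± 0.035 CPM with DMSO. In the guide arm it started higher, at 8.23 to 10.46 CPM with NT1, and ran from 0.39 to 0.67 CPM with MEN1 sg2. Mitosis genes had a lower effect with the drug than with the guide in 26 of 34 (32 adjusted over the list alone; adjusted p = 0.0025), S phase genes in 18 of 34 (25 adjusted over the list alone; adjusted p = 0.0019) and pluripotency genes in 8 of 22 (10 adjusted over the list alone; adjusted p = 0.041), with 1 of 22 the other way. LIN28A differed by -2.36 on the log2 scale (adjusted p = 0.003). It ran from 7.27 to 12.01 CPM with VTP50469 and from 12.95 to 19.14 CPM with MEN1 sg2. The controls differed too, with 2.78 to 3.43 CPM with DMSO and 0.38 to 1.85 CPM with NT1. The difference thus rests in good part on the lower NT1 level. Squamous keratinocyte genes (10 of 15; adjusted p = 9.7e-05), collagen and matrix genes (20 of 36, with 2 the other way; adjusted p = 0.0057), contractile and TGF-beta response genes (11 of 25; adjusted p = 0.00088) and inflammatory and secretory genes (9 of 22; adjusted p = 0.00088) had the higher effect with the drug. These list p-values were taken with an estimated correlation. The comparison holds 1 dose of the drug and 1 guide, in cells that differ also in Cas9, and does not measure how completely either removed menin function. Some genes also started apart in the controls. COL11A1 ran at 214 to 231 CPM with DMSO and 455 to 488 CPM with NT1, and KRT6A at 393 to 427 and 711 to 754 CPM. MCM6 did not, at 64.9 to 73.1 and 69.8 to 71.3 CPM. Differences of effect thus include differences between the controls.

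Finally, genes called with each treatment in infected cells were set against the infection effect of the other arm, whose libraries they do not share. The question was whether menin inhibition or loss moved them with or against the change seen on infection. Of 600 genes called with VTP50469 that infection also changed, 271 went with the infection effect and 329 against it, 45.2% with; independent lists would hold 199 and 200. Of 3219 genes called with MEN1 sg2, 2061 went with it and 1158 against it, 64% with; independent lists would hold 1295 and 1300. NANOG, LIN28A and L1TD1 rose with infection and again with the guide, and COL1A1 fell with infection and again with the guide. KRT6A went against, rising with infection and falling with the guide. Without the library uninfected MEN1 sg2 replicate 2, 406 inhibitor calls went with infection and 536 against it. Leaving out any 1 of the compared libraries gave 146 to 256 with and 161 to 332 against. Without OSKM DMSO replicate 3 the counts were 162 with and 161 against, so the lean of the inhibitor calls against infection was lost there.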

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

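Tests chosen after the result was seen were the repeat of the guide interaction without 1 library, the changes of the factor transcripts, and the ratio, slope and shared direction of inhibitor and guide effects; the thinned libraries and the splits were planned.

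The results of this part were picked out because an effect differed between infected and uninfected cells in a test of that difference. For the inhibitor, 66 genes had a higher and 73 a lower effect in infected cells. The largest differences by the rule for named genes were those of LRRN3 (2.47 on the log2 scale), ZNF483 (2.46) and SLITRK6 (2.37) upward and SLC17A7 (-6.03), IGF2 (-1.92) and RTN4R (-1.89) downward. RTN4R had an adjusted p of 0.046, lost whichever of the 12 compared libraries was left out (0.057 to 0.15). LRRN3 lost its call without OSKM VTP50469 replicate 1 (0.052) or 2 (0.06), OSKM DMSO replicate 2 (0.064), uninfected VTP50469 replicate 1 (0.066) or 2 (0.076) or uninfected DMSO replicate 2 (0.091). SLITRK6 lost it without OSKM DMSO replicate 2 (0.057), uninfected VTP50469 replicate 2 (0.077) or uninfected DMSO replicate 1 (0.074) or 2 (0.1), and ZNF483 without uninfected VTP50469 replicate 1 (0.059). With the replicate as a block LRRN3 (0.067) and SLITRK6 (0.055) were not called, and DESeq2 gave no adjusted p for RTN4R, SLC17A7, LRRN3, SLITRK6 or ZNF483. SLC17A7 had 0 counts with DMSO and 15 with VTP50469 in uninfected cells, against 9.45 ± 1.6 CPM with VTP50469 and 13.6 ± 3.6 with DMSO in infected cells, so its fitted difference depends on the prior count and is no measure of size. For the guide, 871 genes had a higher and 1020 a lower effect in infected cells. PTPRZ1 (7.67), KYNU (5.21) and TRIM71 (5.24) led upward and CADM3 (-5.84), KLK10 (-5.63) and KRT14 (-4.85) downward. KRT14, KLK10 and CADM3 had 0 counts in uninfected NT1 cells and PTPRZ1, KYNU and TRIM71 in uninfected MEN1 sg2 cells, so their fitted differences depend on the prior count and are no measure of size. TRIM71 was no longer called without uninfected NT1 replicate 2 (adjusted p = 0.096). KRT14 was no longer called without uninfected NT1 replicate 1 (adjusted p = 0.058), 2 or 3 (0.059 each), or without uninfected MEN1 sg2 replicate 2 (0.087) or 3 (0.088).

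Other splits of the same libraries were used to ask whether a grouping other than the real one gives as many calls. With 3 libraries against 3, each other split puts 2 libraries of 1 group with 1 of the other on each side. Each side thus mixes the compared groups, and part of the real effect stays. For the comparisons of 3 libraries against 3, the 10 possible splits are too few for a share under 0.05, since the smallest is 0.1. The real split called 738 genes against a highest other of 0 for the inhibitor in infected cells, 479 against 1 in uninfected cells, 4740 against 0 for the guide in infected cells and 3616 against 6 in uninfected cells, and 8218 against 1 and 8106 against 0 for infection with DMSO and NT1. In each of these the real split alone, 1 of 10, reached its value. The mixed groups of the other splits carry the real effect as spread within a group, which by itself leaves few genes to call. These gene counts therefore do not decide whether chance gives as many. For gene lists the real and highest other values were 12 and 11, 10 and 12, 16 and 16, 13 and 10, 13 and 13, and 14 and 16 in that order, and 1, 2, 2, 1, 3 and 5 of the 10 splits called as many as the real one. Camera at its preset correlation thus called many lists in these mixed groupings too. Part of the real effect stays in them, so these counts do not decide how many list calls are false. The estimated correlation is given beside each list as a stricter reading.

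For the interactions 30 splits were drawn. For the genes of the inhibitor interaction 1 split, the real one, reached 139, with a highest other of 101. For the guide interaction 2 splits reached 1891 (highest other 2306), and for inhibitor minus guide 6 reached 1358 (highest other 3053). The splits that called many genes kept the real labels in some pair of groups and so carried a treatment effect. Those that kept them in no pair, 24, 24 and 23 in number, called at most 1, 0 and 1 genes. Their groups mixed treated and control libraries, which shrank the treatment effects together with the interaction and widened the spread within groups. These splits therefore decide for none of the 3 whether chance gives as many genes. For lists 14, 6 and 4 of 30 splits reached the real values of 7, 13 and 17 (highest others 14, 17 and 19). Splits that kept no real pair called up to 9 and 13 lists in the inhibitor and guide interactions and at most 13 for inhibitor minus guide. Treatment effects that remain in such splits can give list calls, so these decide nothing, and chance was not excluded for any of the 3. For genes called alike by inhibitor and guide, 1 of 100 pairs of splits, the real pair, reached 616 in infected cells (highest other 0) and 368 in uninfected cells (highest other 1). For the difference between calls with and against the infection effect, 58 for the inhibitor and 903 for the guide, the highest other was 0 with 1 of 100 pairs each. The other splits called so few genes that no other pair could have reached more than 0, 6, 0 and 1 in these 4 tests, so they decide nothing. Which splits of this paragraph decide nothing was set after their values were seen.

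The guide effect differed between infected and uninfected cells. A single library that stood apart, uninfected MEN1 sg2 replicate 2, is argued against as the whole cause, because 1577 of the 1891 calls were made again in the same direction without it. A difference in library size is argued against too, since 1736 genes were called with all libraries thinned to 6562146 counts, 1643 of them called before in the same direction. What set the difference was not tested further, and the sizes of the leading differences stay open because of the 0 counts in an uninfected group.

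Pluripotency genes were higher with the inhibitor and with the guide in infected cells. More transcript of all 4 factors is argued against, as KLF4 and MYC fell with both treatments. The median log2 fold change of POU5F1, SOX2, KLF4 and MYC was -0.25 with the inhibitor and -0.18 with the guide. For the guide that median covers changes both ways and decides nothing by itself. Library size is argued against for the inhibitor, with 10 list members called after thinning. With the guide POU5F1 and SOX2 rose by a mean of 0.27, which cannot be told apart from an effect of menin loss because the design does not vary the factors separately. A faster or more frequent entry of infected cells into the pluripotency program could also give these values, and was not tested.

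The guide changed more genes than the inhibitor in infected cells, with median standard errors of 0.134 and 0.133. Both come from the fit of all libraries with a shared spread per gene, so they do not compare the spread of the arms. With only the compared groups fitted the inhibitor gave 1521 calls against 738 in the main fit, and the guide 5345 against 4740. Less power in the inhibitor libraries is argued against as the whole cause by the sizes of the effects in infected cells. Over the 3616 genes called with the guide in uninfected cells, whose libraries are separate, inhibitor effects were 0.261 times those of the guide (95% interval 0.222 to 0.301, genes resampled). Over the 479 called with the inhibitor there they were 0.522 times (0.424 to 0.629). Genes are not independent, so these intervals do not measure the spread between libraries, and the ratio depended on how genes were picked. Of the 4740 genes called with the guide in infected cells, 83.4% (3955) went the guide's way with the inhibitor. Part of the guide response was thus shared in direction. Direction does not show what made the guide effects larger, so effects of the guide unrelated to menin stay open as a cause. The slope over those 4740 genes, 0.299, was used first and is lowered by picking them on the guide. Dose, time of exposure and the part of menin function that the inhibitor leaves may each contribute and stay untested.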

How the results depend on the processing

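The fit without uninfected MEN1 sg2 replicate 2 was chosen after the data were examined; the other settings were planned. DESeq2 size factors and upper quartile factors moved no count of genes by over 1.5 times, and shifted the median log2 fold change of all genes by -0.019 to 0.017. Over the 6 planned settings no gene called in any of the 9 comparisons was called in the opposite direction. Of 2136 values of named genes, 252 of them from the fit without uninfected MEN1 sg2 replicate 2, 2112 stayed on their side of the threshold. Another 19 lost and 5 gained a call, 2 of these in that fit, and none reversed. With 1 library left out, 1906 of 1992 stayed, 85 lost and 1 gained a call. Lists kept their side in 1210 of 1350 values, lost the call in 80, gained it in 59 and reversed in 1, with the fit without uninfected MEN1 sg2 replicate 2 included.

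With only the compared groups fitted, the inhibitor in infected cells gave 660 genes higher and 861 lower, the guide in uninfected cells 936 and 1116, the inhibitor interaction 150 and 210, and inhibitor minus guide 1057 lower. This setting estimates the spread from fewer libraries, and for the guide in uninfected cells from a set in which the library that stood apart weighs more. In the fit of the other 23 libraries the inhibitor gave 521 higher and 637 lower in infected and 349 and 529 in uninfected cells, its interaction 159 and 218, shared calls in infected cells 525 lower and 22 opposite, and calls against infection 536. There the ribosomal protein list in the guide interaction changed direction, with an adjusted p of 0.858. DESeq2's Wald test gave 138 genes lower in the inhibitor interaction, the replicate block 11 opposite shared calls in infected and 11 in uninfected cells, and no filter 4 opposite in uninfected cells; the cause was not tested. The numbers of the replicates paired no libraries: over 18 pairs the correlations ran from -0.06 to 0.05.

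With an estimated correlation camera called 5 lists for the inhibitor in infected and 5 in uninfected cells, 10 and 6 for the guide, 0 and 2 for the interactions of inhibitor and guide, and 10 for inhibitor minus guide. Fry, which does not compare a list with other genes, called 25 for the guide in infected cells, 23 and 26 for infection with DMSO and NT1, and 3 for the inhibitor interaction.

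With each library left out in turn, which leaves a group of 2 and fewer degrees of freedom, the ranges were 157 to 222 higher and 222 to 286 lower for the inhibitor in infected cells, 97 to 119 and 180 to 249 in uninfected cells, and 32 to 58 and 30 to 60 for its interaction. Shared calls ranged from 139 to 263 higher, 207 to 339 lower and 2 to 5 opposite in infected cells, and from 75 to 204, 136 to 316 and 2 to 23 in uninfected cells. Inhibitor calls with infection ranged from 146 to 256 and against it from 161 to 332. With all libraries thinned to the smallest total the inhibitor calls went from 738 to 655 in infected and from 479 to 421 in uninfected cells.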

Other observations

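The comparison of HOX paralog groups was planned, and the correlation with transcript length was chosen after the library was seen to stand apart.

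HOX genes fell with the guide in 17 of 18 tested in infected and in uninfected cells, and HOXB2 was the gene not called in each. Infection itself lowered 8 of 18 with DMSO and 6 of 18 with NT1. Ribosomal protein genes, not called as a list, rose in 31 and fell in 4 of 82 on infection with DMSO and rose in 23 and fell in 4 with NT1, and replication-dependent histone genes rose in 9 and 5 of 21.

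A hypothesis held that genes of paralog groups 9 to 13, at the posterior end of the clusters, fell more with the guide than groups 1 to 8. The mean log2 fold changes were -3.28 ± 1.1 (SD, n = 10 genes) and -2.87 ± 1.4 (n = 8 genes) in infected cells, with an exact two-sided permutation p of 0.503 over 43758 splits of the genes. In uninfected cells they were -4.06 ± 0.88 and -3.16 ± 2.19, with an exact two-sided permutation p of 0.266, and both were 0.503 after adjustment over the pair of tests. The plan took any p of 0.05 or more as evidence against the hypothesis. That was wrong, because with 18 genes and this spread a smaller difference cannot be excluded, and the question was left open after the result was seen.

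In the library uninfected MEN1 sg2 replicate 2, the deviation from the mean of the other two correlated with transcript length at -0.25 across 10071 genes, which are not independent replicates and from -0.15 to 0.093 in libraries of the other 7 groups. The 10% of genes with the longest transcripts had a median deviation of -0.23 on the log2 scale in it. The replicate pairs that held it had a chi-square per degree of freedom of 13.6 and 15.2, against 2.34 for the pair without it. Fewer reads from long transcripts, as partial loss of RNA integrity could give, may be part of why it stood apart. A correlation of -0.25 leaves most of the spread of its deviation across genes unexplained, and no measure of RNA quality was used here.

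The mean of the interferon response list varied between libraries of some groups. Its log2 CPM was 4.95, 5.06 and 5.77 in the OSKM NT1 libraries and 4.77, 5.30 and 3.74 in the uninfected NT1 libraries. It was 4.97, 4.80 and 4.97 with VTP50469 and 5.68, 5.54 and 5.58 with DMSO in infected cells, and 4.64, 4.73 and 4.91 against 5.71, 5.21 and 5.44 in uninfected cells. With MEN1 sg2 it was 4.11, 4.27 and 3.86 in infected and 3.92, 4.53 and 4.27 in uninfected cells. Each treated library thus lay below each of its controls in 3 of these 4 comparisons, and the ranges overlapped for the guide in uninfected cells.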
